A study of Homo sapiens with 4 samples.

How the data were processed

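The series holds 4 bead arrays of U87 cells, 2 transfected with a piR-598 mimic and 2 with an NC oligo, at 25 nM and sampled at 24 h. Per the labels, the control was a commercial negative control made for microRNA inhibitors, while the piR-598 molecule was a synthetic mimic. Per the labels' protocols, total RNA was extracted with a kit that also recovers short RNAs, and biotin-labelled cRNA was made with the Illumina TotalPrep kit. Samples were assigned to groups and replicate numbers from their titles. The labels describe biological duplicates and name no shared day or batch. Slide and array position were not used here.

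The authors deposited 2 tables. The first holds an average signal intensity per probe and array with a detection p-value beside each, as deposited by the authors and named in the file headers. Per the submitters' processing notes, GenomeStudio 2011.1 was used. These intensities were on a linear scale, showed no background subtraction (lowest value 72.8) and had array means from 273.0 to 305.8. The detection p-values moved in steps of 1 in 770. Each detection column followed the signal column it stood beside, with a rank correlation of -0.983 or stronger. The second table holds scaled intensities deposited by the authors. Set against the first, each of its columns was the unscaled signal times a constant (0.951, 0.970, 1.07 and 1.02 for NC oligo 1 and 2 and piR-598 mimic 1 and 2), which brought every array mean to 291. Its medians were 94.6, 96.5, 99.8 and 97.8 in that order. It is linear, not centred and holds signals, not ratios, so scale, centring and direction were all settled. It was used as an alternative only.

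The unscaled signals were background-corrected by normexp, with the negative control mean and SD inferred from the detection p, and an offset of 16. They were then quantile normalized and taken to log2 (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, 20188 of 47318 or 42.7%. Each probe was tested with lmFit and eBayes in limma, piR-598 mimic minus NC oligo, with Benjamini-Hochberg adjustment over probes and calls at an adjusted p under 0.05. All tests were two-sided. The fitted prior carried 6.74 degrees of freedom. With 2 arrays per group, the spread estimate of each probe leans on the spread of all probes. The labels do not say whether the duplicates came from separate passages, so p-values measure only the spread between these samples.

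Genes were named from the platform annotation, in which 30112 probes had 1 symbol, 8 several and 17198 none. Of the named probes 30073 were matched by gene identifier to the RefSeq table of assembly GRCh38.p14, and 0 symbols needed updating. No coordinates were used. Of the tested probes 4776 had no single symbol, and they took part in the probe counts only. For the gene lists, each gene was represented by its detected probe of highest mean signal. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the 25 lists with at least 3 measured genes. Camera with an estimated correlation and fry were alternatives. The 29 lists held 514 genes, of which 34 matched no named probe used here. A detected probe was held by 407, and the remaining genes entered no list test.

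The genes named in the text follow a rule fixed before the data were examined. It takes up to 12 called genes per direction whose arrays separate by group. Where fewer were called, it fills each direction to 12 with the smallest unadjusted p among separated probes with exactly 1 symbol. It adds the 3 members of smallest unadjusted p of each list, and PIWIL1 to PIWIL4 whatever their values. A probe detected on no array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group and, per array of the dimmer group, the higher of the probe's own value and the lowest value among detected probes. This bound allows for the detection limit only, not for the spread between arrays.

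The steps were tested on simulated data with the real probe means. The spread of each probe was drawn from the fitted prior, and noise was independent between probes. With 200 changed probes placed among the simulated probes, limma recovered 0 of 49 at 1.5-fold, 21 of 50 at 2-fold, 40 of 47 at 3-fold and 39 of 49 at 4-fold, with 9 false calls among 20122 unchanged probes. Both lists shifted by a log2 of 0.5 were recovered among 25, with 0 others called. That shift is larger than any real list mean, which ran from -0.09 to 0.07. Genes that vary together were not simulated, so this does not show the recovery or false calls of real lists.

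Alternatives fixed beforehand were no background correction, an offset of 50, median scaling, cyclic loess, no detection filter, a detection p under 0.01 on all 4 arrays, the authors' scaled signals and an intensity trend in eBayes. Further ones were the replicate number as a block, 1 probe per gene, the dimmest probe per gene for lists, and leaving out each array in turn. When an array is left out, the lone array of its group is assumed to vary like the other group.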

Results

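Gene expression was measured on Illumina bead arrays in U87, an established human glioblastoma cell line. The cells had been transfected at 25 nM with a synthetic mimic of piR-598, a PIWI-interacting RNA, or with a negative control oligo (NC oligo). PIWI-interacting RNAs are short RNAs that work with PIWI proteins, best known for silencing transposons in the germ line. RNA was collected 24 h after transfection. There were 2 arrays per group, described by the submitters as biological duplicates, and each array carried 47318 probes. The mean deposited signal was 305.8 and 300.0 on NC oligo arrays 1 and 2, and 273.0 and 284.8 on piR-598 mimic arrays 1 and 2. A detection p under 0.05 was reached by 20157 and 19627 probes on the NC oligo arrays and by 20324 and 19698 probes on the piR-598 mimic arrays. The number of arrays limits the precision of every value given here.

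After normalization all 6 pairs of arrays were closely similar, and the arrays did not group by treatment. Across the tested probes, Pearson's r was 0.994 between the NC oligo arrays and 0.991 between the piR-598 mimic arrays. These correlations are across probes, which are not independent replicates. The SD of the log2 difference was 0.23 between the NC oligo arrays and 0.29 between the piR-598 mimic arrays. Pairs taken across the groups lay between 0.23 and 0.28. The spread between the 2 piR-598 mimic arrays was thus larger than that of any pair made of a mimic and an NC oligo array.

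The comparison of the groups asks which transcripts differ 24 h after transfection of the piR-598 mimic. No transcript passed the test. Among the genes named by the rule fixed beforehand, the values furthest from 0 were those of PIGV, MMS19, RNY5, EID2B and RNU1-3, lower with the mimic, and of SOX30 and WASHC1, higher with it. Of 20188 probes tested with limma, representing 11704 named genes, 0 were called at a Benjamini-Hochberg adjusted p under 0.05, with 0 higher and 0 lower. The smallest adjusted p from limma was 0.895. At an unadjusted p under 0.05 there were 1102 probes, 529 higher and 573 lower with the mimic, where 1009 would be expected with no effect. That is 5.46% of the tested probes, against 5.97% of the unchanged probes in simulated data. The count was 471 without NC oligo replicate 1, 658 without NC oligo replicate 2, 1444 without piR-598 mimic replicate 1 and 2285 without piR-598 mimic replicate 2. Without NC oligo replicate 2, limma called 3 probes with no gene name, and without piR-598 mimic replicate 2 it called 1, for TELO2, which was bright on mimic array 1 alone. The 4 arrays separated by group at 7004 probes, or 34.7%, against 33.3% by chance. The median 95% interval of a log2 fold change reached 0.35 to either side, which corresponds to 1.28-fold. For 20070 probes, or 99.4%, that interval lay within a 2-fold change in either direction, and for 15068 probes, or 74.6%, within 1.5-fold. In data simulated for this comparison, 0 of 49 probes changed by 1.5-fold were recovered, 21 of 50 changed by 2-fold and 40 of 47 changed by 3-fold. Their fitted changes were too small, with a median log2 size of 0.45 at 1.5-fold, 0.82 at 2-fold and 1.30 at 3-fold. The intervals above are of fitted values, so they bound the true changes less tightly.

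Only 3 tested probes differed by 2-fold or more, and they were picked out after their values were seen. PIGV, a mannosyltransferase of GPI anchor synthesis, had a log2 fold change of -1.10 ± 0.21 (SE). The other 2 probes are named by no gene in the annotation used here. Probe ILMN_3290035 had a log2 fold change of 1.52 ± 0.50 (SE), which was 0.51 without NC oligo replicate 1 and 2.52 without NC oligo replicate 2. Probe ILMN_3268697 had -1.16 ± 0.45 (SE), which was -0.34 without piR-598 mimic replicate 2 and -1.98 without piR-598 mimic replicate 1. An unadjusted p under 0.01 together with at least a 1.5-fold change was met by 64 probes, 22 higher and 42 lower with the mimic. Before any requirement on fold, 151 probes had an unadjusted p under 0.01, where 202 would be expected with no effect. The count of 64 depended on the processing: it was 2 without background correction, 7 with an offset of 50, 100 with median scaling and 1 on the authors' scaled signals. It was 67 without NC oligo replicate 1, 123 without NC oligo replicate 2, 194 without piR-598 mimic replicate 1 and 444 without piR-598 mimic replicate 2.

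**Figure D1:**
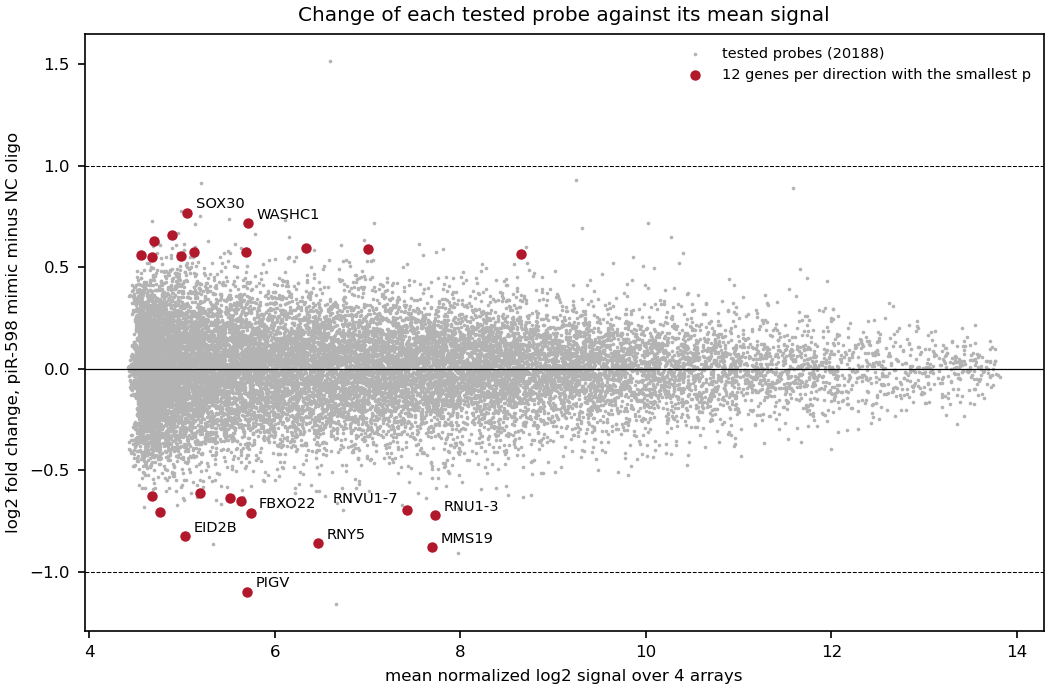
Log2 fold change (piR-598 mimic minus NC oligo) of each of the 20188 tested probes against its mean normalized log2 signal over the 4 arrays. Red points are the 12 genes per direction with the smallest unadjusted p, dashed lines mark a 2-fold change, and 3 probes lie beyond them.

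The 12 genes with the smallest unadjusted p among those higher with the mimic did not pass the test, and each is given as a value only. SOX30, a SOX-family transcription factor best known from testis, had a normalized log2 signal of 5.44 ± 0.11 with the mimic and 4.67 ± 0.00 with the NC oligo (SD, n = 2). Its log2 fold change was 0.77 ± 0.14 (SE). WASHC1, a subunit of the endosomal WASH complex with near-identical gene copies that its probe may not tell apart, had 0.72 ± 0.18 (SE). GRB2, the adaptor that links receptor tyrosine kinases to Ras, had 0.59 ± 0.15 (SE), and ERP29, an endoplasmic reticulum chaperone, had 0.59 ± 0.14 (SE). The log2 fold changes were 0.57 for RIMKLA, 0.57 for CTTN, which encodes the actin-binding protein cortactin, and 0.57 for SS18, a subunit of the BAF chromatin remodelling complex. ZDBF2, an imprinted gene, was detected on 1 of 2 NC oligo arrays and had a log2 fold change of 0.66. SLAMF7, a receptor known from immune cells, had 0.56. The remaining 3 were not well above background on either NC oligo array. SLC6A20, an amino acid transporter, was at least 1.34-fold higher with the mimic, the deubiquitinase OTUD7B at least 1.28-fold and the olfactory receptor OR4C12 at least 1.18-fold. These lower bounds did not pass the test either (limma adjusted p = 0.895 for all 12 genes).

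The 12 genes with the smallest unadjusted p among those lower with the mimic did not pass the test either (limma adjusted p = 0.895 for each). MMS19, which acts in cytosolic iron-sulfur protein assembly, had a normalized log2 signal of 7.26 ± 0.08 with the mimic and 8.14 ± 0.12 with the NC oligo (SD, n = 2). Its log2 fold change was -0.88 ± 0.15 (SE). In addition to PIGV, this group held 3 short structural RNAs: the Y RNA gene RNY5, with a log2 fold change of -0.86 ± 0.17 (SE), and the U1 small nuclear RNA genes RNU1-3, with -0.72 ± 0.15 (SE), and RNVU1-7, with -0.69 ± 0.15 (SE). U1 genes have near-identical copies, so which copy these probes read is uncertain. EID2B had -0.82 ± 0.18 (SE) and was detected on 1 of 2 mimic arrays. FBXO22, the substrate-binding subunit of a ubiquitin ligase, had a log2 fold change of -0.71, and GBP1, an interferon-induced GTPase, had -0.65. RPS6KA5, a kinase that phosphorylates histone H3 and CREB, had -0.64, and the palmitoyltransferase gene ZDHHC11 had -0.61. GRAMD2B and BCL7A, a BAF complex subunit, were not well above background on either mimic array. They were at least 1.45-fold and at least 1.33-fold lower with the mimic.

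**Figure D2:**
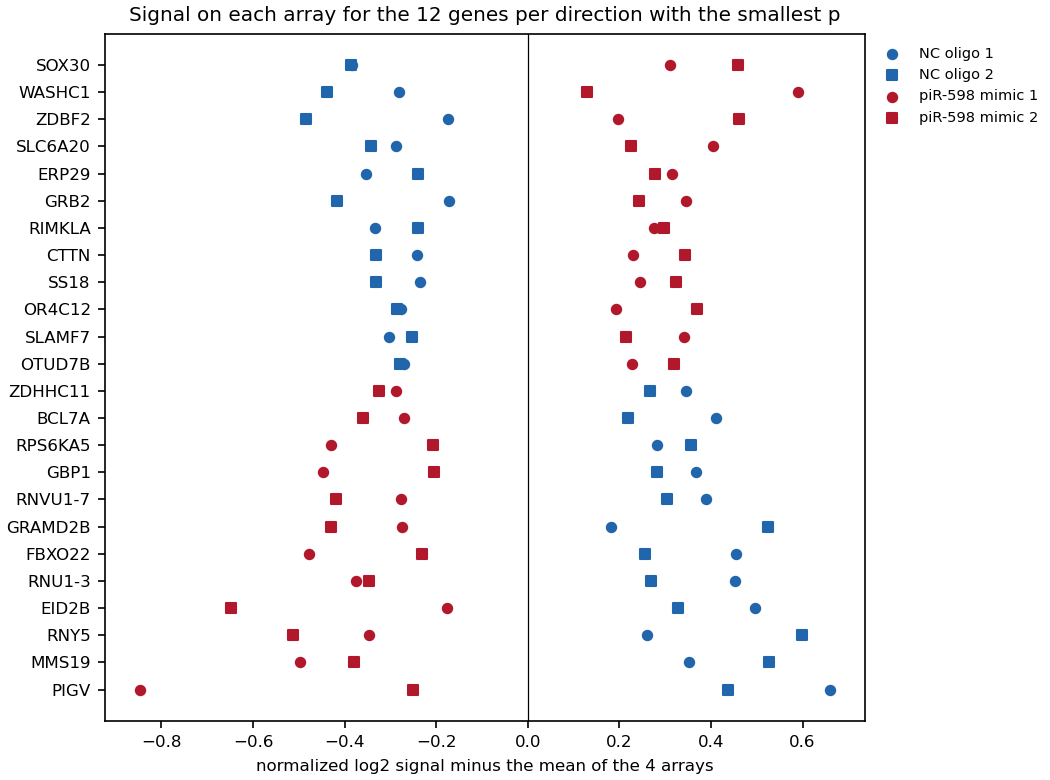
Normalized log2 signal of each array minus the mean of the 4 arrays, for the 12 genes per direction with the smallest unadjusted p among probes whose arrays separate by group. Blue points are NC oligo arrays and red points piR-598 mimic arrays, with circles for replicate 1 and squares for replicate 2; none of these genes passed the test (limma adjusted p = 0.895).

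For 11 of these 24 genes, at least 1 other probe of the same gene was also tested, and in 0 of the 11 did the other probes average a 1.5-fold change in the same direction. The other probe had a log2 fold change of 0.01 for SOX30, 0.08 for WASHC1, -0.09 for ERP29 and 0.05 for GRB2. CTTN had 2 other probes at 0.01 and 0.03, and SS18 had 2 at 0.28 and -0.01. Among the genes of the lower group, the other probe was at 0.02 for MMS19, -0.05 for FBXO22 and -0.23 for GBP1. It was at 0.35 for EID2B and 0.20 for BCL7A, opposite in sign to the probe named above. The median of the other probes, taken in the direction of the named probe, was 0.02 against 0.65 for the named probes themselves.

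Of 29 gene lists fixed before the data were examined, 25 had at least 3 measured genes, and 0 of these shifted against the other genes (camera in limma, smallest adjusted p = 0.956). At an unadjusted p under 0.05 there were also 0 lists. With an estimated correlation, camera called 0 lists (smallest adjusted p = 0.974), and fry called 0 (smallest adjusted p = 0.967, or 0.347 for change in either direction). Camera with an estimated correlation takes its degrees of freedom from the few arrays, so it had little power to call a list. Of 407 distinct listed genes with a detected probe, 0 passed the test over all probes, 0 passed when adjusted over the list alone, and 14 had an unadjusted p under 0.05. Mean log2 fold changes of the tested lists ran from -0.09 to 0.07. Median scaling moved the median of the tested probes to -0.09. List means and genes under the 5 other scalings or background settings are therefore set against the median of the tested probes in each. Such values are written as relative to all probes, meaning all tested probes. So measured, the mean changed sign under at least 1 of the 5 for 10 of the 25 lists, as named with each list. Single arrays weighed on the members as well: of the 80 list genes named here, 52 shrank by over 1.5 times and 10 turned sign when some array was left out. The mean, the median and the direction of the test differed in sign for 9 lists. Without piR-598 mimic replicate 1, camera at the preset correlation called the G2/M and mitosis genes, with a mean of 0.15. Without piR-598 mimic replicate 2 the mean was -0.07. That list was not called with an estimated correlation, but on so few arrays that form could hardly call any list, so it cannot decide. Of the list members named here, another tested probe of the gene had the opposite sign for TNFRSF10B, CASP6, BIRC2, BCL2L1, NQO1, LAMP2, PLD6, RTEL1, SNAP25, MAP2 and TEK. For CANX and B2M the other probe was nearer to 0, at -0.02 and 0.05.

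Genes that respond to foreign RNA, to damage or to cell death signals had members on both sides of 0. The 31 measured interferon-stimulated genes had a mean log2 fold change of 0.03, at -0.0031 relative to all probes on the authors' scaled signals, with 16 positive and 15 negative. OAS1, a sensor of double-stranded RNA, had 0.52 ± 0.18 (SE) and IFIT2 had -0.32 ± 0.14 (SE). IFI27, not well above background on the NC oligo arrays, was at least 1.16-fold higher with the mimic. The 21 NF-kB and inflammatory cytokine genes had a mean of -0.03. Among them CXCL1 had a log2 fold change of -0.26, RELB -0.26 and IL1B 0.23. The 22 p53 target genes had a mean of -0.02, with BAX, a pore-forming effector of apoptosis, at 0.41 ± 0.14 (SE), DDB2 at 0.30 and PPM1D at -0.35. The 20 pro-apoptotic genes had a mean of -0.01, with TNFRSF10B, a TRAIL receptor, at -0.29, CASP6 at 0.25 and BAX again among them. The 11 anti-apoptotic and survival genes had a mean of -0.04, with BIRC2 at -0.35 (-0.07 without piR-598 mimic replicate 1), BCL2L2 at -0.17 and BCL2L1 at 0.15. None of these genes passed the test (limma adjusted p of at least 0.895).

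Neither cell cycle list was called with all 4 arrays. The 30 G1/S and DNA replication genes had a mean log2 fold change of 0.04, and of -0.02 relative to all probes on the authors' scaled signals. The replication licensing factor CDC6 had 0.40 ± 0.15 (SE), GINS4 had 0.55 ± 0.21 (SE) and FEN1 had 0.25 ± 0.14 (SE). The 30 G2/M and mitosis genes had a mean of 0.04, with 21 positive and 9 negative, and of -0.02 relative to all probes on the authors' scaled signals. The proliferation marker MKI67 had 0.53 ± 0.20 (SE), the spindle checkpoint kinase BUB1B had 0.38 ± 0.17 (SE), and ECT2 had -0.37 ± 0.23 (SE). Without piR-598 mimic replicate 1 ECT2 was at 0.01, without piR-598 mimic replicate 2 MKI67 was at 0.26, and without NC oligo replicate 1 GINS4 was at 0.22. None of these 6 genes passed the test (limma adjusted p of at least 0.895).

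No stress or metabolic list was called. The 17 endoplasmic reticulum chaperone and unfolded protein response genes had a mean of 0.01, at -0.02 relative to all probes under median scaling and -0.03 on the authors' scaled signals. In that list CANX, the lectin chaperone calnexin, had a log2 fold change of -0.35, SDF2L1 0.23 and PDIA6 0.24. The 22 ATF4 and amino acid response genes had a mean of -0.01, with NUPR1 at 0.43 and the transporter SLC7A5 at 0.27. ALDH1L2, of the same list, was not well above background on the mimic arrays and at least 1.18-fold lower there. The 19 cholesterol synthesis and uptake genes had a mean of 0.00, at -0.02 relative to all probes both under median scaling and on the authors' scaled signals, with MVD at -0.35, IDI1 at 0.26 and SC5D at -0.22. The 14 heat shock genes had a mean of 0.03, at -0.0025 relative to all probes on the authors' scaled signals, with HSPA1B at 0.36, HSPA4 at -0.17 and DNAJB1 at 0.17. The 25 hypoxia and glycolysis genes had a mean of -0.06, with 16 negative, among them HK2 at -0.29, BNIP3 at -0.20 and P4HA1 at -0.17.

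The 12 NRF2 target genes had a mean of -0.01, with NQO1 at -0.24, TKT at 0.15 and SRXN1 at -0.11. The 7 metallothioneins had the highest mean of any tested list, 0.07, with MT1X at 0.20, MT1H at 0.15 and MT1M at 0.10. Relative to all probes the list mean was 0.06 under median scaling. It was 0.036 on the authors' scaled signals, where the microglia and macrophage markers were higher at 0.043. The 26 oxidative phosphorylation genes had a mean of -0.02, with NDUFS1 at -0.35, NDUFB5 at -0.22 and SDHD at -0.26. The 21 autophagy and lysosome genes had a mean of 0.00, at -0.03 relative to all probes under median scaling, -4.7e-04 with cyclic loess and -0.04 on the authors' scaled signals, with ATP6V0D1 at 0.23, ATG5 at -0.17 and LAMP2 at -0.15. The 19 immediate early and MAPK feedback genes had a mean of -0.01, with the receptor kinase antagonist SPRY2 at -0.41, IER3 at 0.29 and SPRED1 at -0.21. The 20 extracellular matrix and mesenchymal genes had a mean of 0.02, at -0.02 relative to all probes on the authors' scaled signals, with CCN1 at 0.43, FN1 at 0.43 and COL1A1 at 0.27. None of the genes named for these stress, metabolic, MAPK and matrix lists passed the test (limma adjusted p of at least 0.895).

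**Figure D3:**
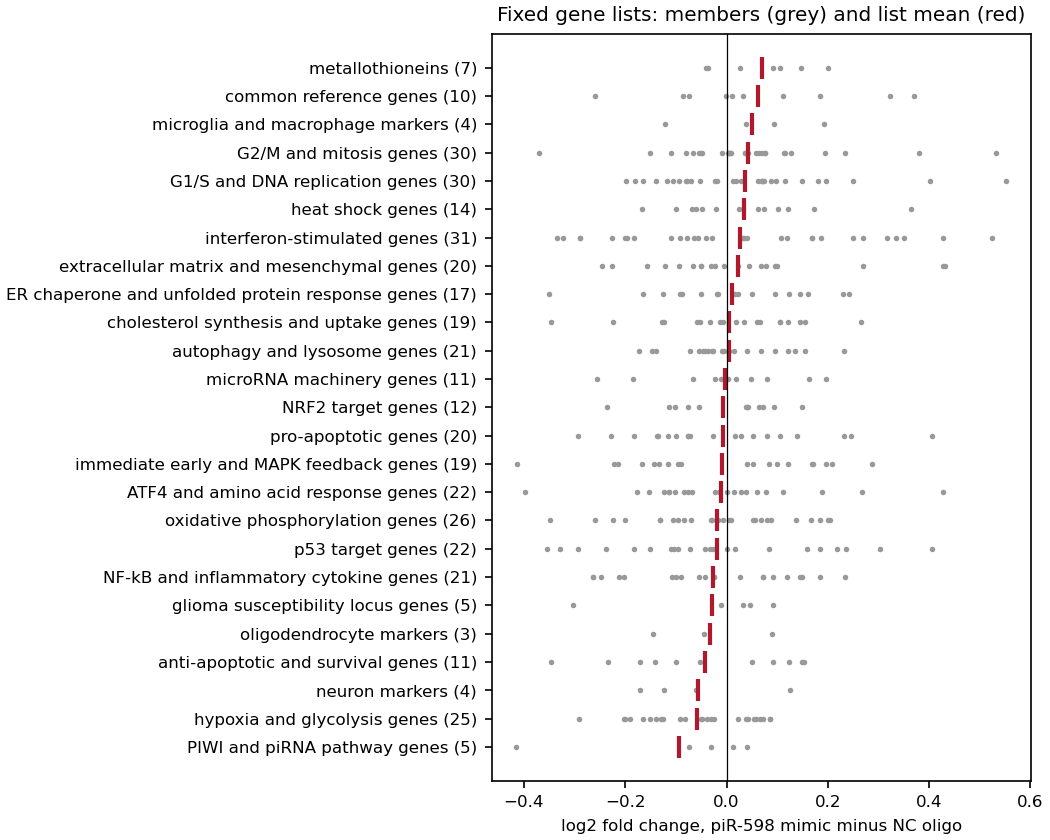
Log2 fold change (piR-598 mimic minus NC oligo) of the measured genes of each of the 25 tested lists (grey points, 1 probe per gene) with the list mean (red bar); the number of measured genes is in parentheses. List means lie between -0.09 and 0.07, 10 of them change sign relative to all tested probes under at least 1 of 5 other scalings or background settings, and no list was called.

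The PIWI genes themselves were not detected. PIWIL1, PIWIL2, PIWIL3 and PIWIL4 encode the proteins that bind PIWI-interacting RNAs, and each of their 6 probes was detected on 0 of the 4 arrays. Their detection p ran from 0.0701 for PIWIL4 to 0.925 for PIWIL2, so no fold change is given. In the PIWI and piRNA pathway list, 5 of 19 genes were measured, with a mean log2 fold change of -0.09. TDRKH, a Tudor-domain partner of PIWI proteins, had -0.42 ± 0.15 (SE) and was detected on 1 of 2 mimic arrays. TDRD6, detected on 1 of 2 arrays in each group and so near the detection limit, had -0.07 ± 0.20 (SE), at 0.0053 relative to all probes on the authors' scaled signals. PLD6 had 0.04 ± 0.14 (SE), at -0.0082 relative to all probes under median scaling and -0.02 on the authors' scaled signals. The 11 microRNA machinery genes had a mean of 0.00, slightly below 0 and at 0.0022 relative to all probes without background correction and 8.4e-04 with an offset of 50, with DICER1 at -0.26, PRKRA at -0.18 and TNRC6A at 0.16. Of 9 genes at glioma susceptibility loci, 5 were measured, with a mean of -0.03. TERC, the telomerase RNA, had a log2 fold change of -0.30 ± 0.14 (SE), and RTEL1 had 0.05 ± 0.15 (SE). CDKN2B, also detected on 1 of 2 arrays in each group, had 0.09 ± 0.16 (SE). The 10 common reference genes had a mean of 0.06, with PPIA at 0.37, B2M at 0.32 and HPRT1 at -0.26. None of these genes passed the test (limma adjusted p of at least 0.895).

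Most markers of other cell types were not measured here, and those measured did not pass the test (limma adjusted p of at least 0.895). Of the astrocyte markers 2 of 7 were measured, the gap junction gene GJA1 at a log2 fold change of -0.41 and the glutamate transporter SLC1A3 at -0.12. Of the neuron markers 4 of 8 were measured, with a mean of -0.06, SNAP25 at -0.17, TUBB3 at 0.12 and MAP2 at -0.12. Of the oligodendrocyte markers 3 of 8 were measured, with a mean of -0.03, at 0.02 relative to all probes under median scaling and 0.01 on the authors' scaled signals. OLIG2 had -0.14, MAG, detected on 1 of 2 NC oligo arrays, 0.09, and CNP -0.05, the last at 0.01 relative to all probes in both settings. Of the microglia and macrophage markers 4 of 8 were measured, with a mean of 0.05. CSF1R had 0.19, AIF1 -0.12 and CD68 0.09. The other probes of CD68 were at 0.07 and 0.56. The endothelial markers KDR and TEK were the 2 measured of 6. KDR was not well above background on the NC oligo arrays and at least 1.14-fold higher with the mimic, and TEK had -0.26. EPCAM, the 1 epithelial marker of 5 that was measured, was detected on 1 of 2 mimic arrays and had -0.12. NES, the 1 neural stem marker of 3 that was measured, had -0.04.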

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

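The alternatives here were fixed before the data were examined. With all 4 arrays, limma called 0 probes and camera or fry called 0 lists under every setting tried, among them cyclic loess, no detection filter and an intensity trend. The count of probes at an unadjusted p under 0.01 and at least 1.5-fold, 64, moved to 2 without background correction and 7 with an offset of 50. Both settings by construction shrink fold changes more than the main setting. The count was 1 on the authors' scaled signals, which differ in both background and scaling. It was 100 with median scaling. That setting equalizes the median over all 47318 probes of an array, and it left the tested probes at a median of -0.09. Why the count rose was not tested. With fewer probes tested, it was 42 at a detection p under 0.01 on all arrays and 33 with 1 probe per gene. With no detection filter, where all 47318 probes were tested, it was lower as well, at 44.

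Leaving out each array in turn gave 67 to 444 such probes, 0 to 3 called probes (0 to 3 higher) and 0 to 1 called lists. Without NC oligo replicate 2, limma called 3 probes named by no gene, ILMN_3290035, ILMN_3278157 and ILMN_3280565, all dim on NC oligo array 1 alone. Without piR-598 mimic replicate 2, it called TELO2 (log2 fold change 1.72, adjusted p = 0.0327), bright on mimic array 1 alone. Without piR-598 mimic replicate 1 the called list was the G2/M and mitosis genes.

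With the replicate number as a block, limma called 0 probes, with 1438 at an unadjusted p under 0.05, and 88 met the 1.5-fold criterion. Deviations of same-numbered arrays correlated at 0.147 over probes, and 2 pairs are too few to show pairing. A fit with the slide as a block was not run.

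The 24 genes named by smallest p were chosen for arrays that separate by group, so their sign cannot change when an array is left out. It changed in 0 of the 24 under the 5 other scalings or background settings, but the sizes shrank where more background was left in the signal. Relative to all probes, SOX30 went from 0.77 to 0.38 with an offset of 50 and 0.24 without background correction. PIGV went from -1.10 to -0.66 and -0.44 in the same settings. Over all named genes 1403 of 1427 alternative values kept their sign, and 24 values of genes that were never called changed sign. List means kept sign and side of the threshold in 336 of 400 alternatives and changed sign uncalled in 63. Some of those sign changes follow from the shift of the tested probes under median scaling. Relative to all tested probes, 15 of the 25 list means kept their sign under the 5 scaling and background settings. Below the lowest detected signal, a log2 value of about 4.6 after normalization, no fold can be measured.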

Other observations

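All tests in this part were chosen after the values were seen, except the comparison of scalings for the small nuclear RNA probes, whose criterion was set before its values were seen. Among transcripts outside the fixed lists, probes for small nuclear RNAs and Y RNAs were mostly lower with the mimic, while 101 small nucleolar RNA probes had a median log2 fold change of -0.03. Small nuclear RNAs are mostly the RNA cores of the splicing machinery and related particles. The class used here is the RefSeq label of the named gene, and it also takes in 7SK and snaR. Of 16 tested probes with that label, 15 were lower with the piR-598 mimic, with a median log2 fold change of -0.31. Whether the probes for short RNAs read the mature short RNA could not be checked. Their values are therefore probe signals and may not follow the amount of that RNA. U1 probes averaged -0.66, and the U4atac probe, of the minor spliceosome, had -0.60. The U11, U4, U6atac and U6 families averaged -0.31, -0.30, -0.27 and -0.26, the snaR probe had -0.16, and the U5 probe was lower but not well above background on either mimic array (measured difference -0.13). The 7SK probes averaged 0.07, with -0.16 and 0.30 for its 2 probes. Of 4 Y RNA probes 3 were lower (RNY5 -0.86, RNY4 -0.49, RNY1 -0.19) and RNY3 was at 0.15. Of 14 RNA classes tested with camera at a preset correlation, small nuclear RNAs (adjusted p = 3.16e-09) and Y RNAs (adjusted p = 0.0289) were called. Neither call held with an estimated correlation (adjusted p = 0.293 with an estimated correlation for small nuclear RNAs and 0.469 for Y RNAs). Before adjustment, camera with an estimated correlation gave p = 0.0209 and p = 0.10 in that order. The estimated correlations were -0.0016 and -0.29, both below the preset value, so a higher correlation between probes did not remove the calls. With an estimated correlation, camera takes its degrees of freedom from the few arrays, and at a preset one from the many probes. That leaves the estimated form little power, so the lost calls count neither for nor against a shift. The p-values at a preset correlation are taken across probes, which are not independent replicates. No single probe of these classes passed limma's test (adjusted p of at least 0.895).

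The lower median of the small nuclear RNA probes was set neither by a single array, being -0.27 or lower without any 1 of the 4, nor by near-identical U1 copies, since the median over the other families was -0.27. Scaling alone hardly moved it: relative to all tested probes the median was -0.31, and it was -0.28 with median scaling and -0.30 with cyclic loess. It shrank where more background was left in the signal, to -0.17 with an offset of 50 and -0.13 without background correction, and was -0.11 on the authors' scaled signals, which differ in both background and scaling. A loss of all short RNAs alike predicts lower small nucleolar RNA probes. Of these, 25 matched on mean signal to 13 of the 16 probes had a median of -0.017 (95% bootstrap interval -0.10 to 0.08). Some may read the host transcript, so such a loss cannot be excluded. Among probes for other short structural RNAs, TERC was lower at -0.30 ± 0.14 (SE). RPPH1 (RNase P) at -0.15 ± 0.17 (SE) and 5S ribosomal RNA at -0.17 ± 0.20 (SE) differed by less than their SE. RMRP was not well above background on either mimic array (measured difference -0.45). The 7SL probe, at 0.14 ± 0.16 (SE), also differed by less than its SE, and vault RNA probes are given below. Also open are a batch or RNA preparation difference that affects some short RNAs and not others, and the unlike chemistry of mimic and control oligo. So is an effect of the mimic, and none of these was tested.

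The probes that met both thresholds were, as a set, not matched by other probes of the same genes. Genes outside these thresholds were not examined in this way. Of the 64 probes with an unadjusted p under 0.01 and at least 1.5-fold, 19 belong to genes with another tested probe. The other probes of those genes had a median log2 fold change of 0.0096 in the same direction (95% bootstrap interval -0.07 to 0.08), against 0.64 for the 19 themselves, and 0 of 19 averaged 1.5-fold. For these genes as a set, that argues against a change in all of their transcripts, with LEMD3 an exception (-0.38 in its other probe against -0.59). Chance in single probes and a change in 1 transcript variant stay open, and probe sequences were not used here.

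Splitting the 4 arrays by replicate number gave more probes at an unadjusted p under 0.05 than splitting them by treatment, 1529 against 1102, with 0 called by limma in both (smallest adjusted p 0.0531 and 0.895). The third split, across both, gave 650. Counting the split by treatment itself, 2 of the 3 splits gave at least 1102, and 3 splits are too few for a share under 0.05. A shared day or batch of same-numbered samples may underlie this and predicts that differences between replicates 1 and 2 correlate across the groups. That correlation was 0.147 over probes, and with 2 pairs a shared batch cannot be told apart from unrelated differences between arrays.

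Ribosomal RNA probes had a median log2 fold change of 0.24 over 4 probes, which was -0.10 without NC oligo replicate 1 and 0.58 without NC oligo replicate 2. Vault RNA probes had a median of -0.32, which was -0.10 without NC oligo replicate 1 and -0.50 without NC oligo replicate 2. All 3 were below 0, with VTRNA2-1 at -0.34 ± 0.20 (SE) and VTRNA1-1 at -0.32 ± 0.18 (SE). VTRNA1-2, at -0.06 ± 0.14 (SE), was hardly changed. The 53 probes for microRNA genes had a median of 0.00.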
